A study of Mus musculus with 5 samples.

How the data were processed

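The series holds 5 CUT&RUN libraries of neonatal mouse cardiomyocytes: 2 of control-treated cells and 2 of Kdm5b knockdown cells for H3K4-enriched chromatin, and 1 negative control of control-treated cells. Chromatin was prepared with a commercial CUT&RUN kit and libraries with an Illumina DNA library kit, per the labels' protocols. Reads were trimmed with Trim Galore and referred to the mouse build GRCm39, per the submitters' processing notes. The aligner, the peak caller, the merging of peaks across libraries, the counting tool and the rule that assigns a peak to a gene were not given in the sources used here. The authors deposited 1 table of CPM values per peak and library, with a peak name that carries the position and a gene symbol. Positions are printed as that table gives them, and no annotation of exons or promoters was used. A gene table of another build was at hand and none of its coordinates were used.

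Each deposited CPM value was a whole multiple of 1 step per column, which gave back whole reads for 100% of the values within a tolerance of 1e-06, so the CPM are reads scaled to the total of reads in peaks. Totals in peaks ranged from 3784381 (negative control) to 31068085 (knockdown library 4). For this work 2 lines of the table had been emptied, which held between 218 and 1561 reads per library and stayed in the totals. All 5 value columns were used and 0 were left out. The H3K4 column names carry numbers that the sample titles do not, so a column was mapped to its group and not to a single titled sample. The authors' values share a fixed total per library, which ties the level of every peak to that of all others.

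Values were analysed as log2(CPM + 1), so a fold change is on that scale and understates the change of low peaks. Peaks with at least 1 CPM in at least 2 of the 4 H3K4 libraries were tested, 58072 of 85275. The comparison of knockdown with control used limma's linear model with an intensity trend (lmFit and eBayes with trend, 2-sided) on the 4 H3K4 libraries, with Benjamini-Hochberg adjustment over all tested peaks and a threshold of 0.05. Its prior degrees of freedom were infinite, so the spread of a peak was taken from peaks of the same height. SE values are those of this fit. Gene lists were tested with camera at a preset correlation of 0.01 on 1 peak per gene, the peak with the highest mean CPM among those the table assigns to the gene, with Benjamini-Hochberg adjustment over 27 lists of at least 5 measured genes. Camera with an estimated correlation and fry were run as second tests, and 0 list calls held with either. In fry the adjusted p of the G2/M list was 0.054, and that of the epicardial, sarcomere and calcium handling lists was 0.069. The negative control was compared through ratios on the same log2 scale, with at least 2-fold above it counted as enriched. For random lists, 10000 draws matched on mean signal were used and their central 95% is given.

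The 28 gene lists (629 genes, 506 of them measured, some in more than 1 list), the design, the tests, most of the other settings and the rule for named genes were fixed before the data were examined. Named genes were the 10 largest rises and the 10 largest falls among peaks past the threshold with both knockdown libraries on the same side of both control libraries, a mean of at least 5 CPM and a gene symbol that is neither a Gm number, a Rik clone nor an unnamed locus, 1 peak per gene. Added to these were a fixed set of cell-cycle, cardiac, marker and control genes, whatever their values, and in each list the 2 to 4 members with the smallest p. Members of a list that passed the threshold beyond this rule (Dab2, Mcm2 and Wt1) were named after their values were seen. Of the 10 largest rises, 1 is not reported here.

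The other settings chosen in advance were pseudocounts of 0.5 and 5, no filter, a filter of 5 CPM, only peaks 2-fold above the negative control, TMM scaling, quantile normalization, median centring, limma without a trend or with robust settings, the number in the column names as a block, each library left out in turn, other thresholds, and for the lists the second tests and the average of all peaks of a gene. With 1 library left in a group, that library is assumed to vary like the other group. Chosen after seeing the data were edgeR's quasi-likelihood test on the recovered reads with library totals or TMM, DESeq2 on the same reads, cyclic loess normalization and scaling on peaks under 500 bp that lie below the negative control. On the recovered reads edgeR with library totals called 634 peaks higher and 712 lower. DESeq2 gave 39406 peaks no adjusted p under its own filter, and these stayed out of its counts. A result counts as reversed where its sign changed and it was past the threshold in at least 1 of the settings compared, and a list takes its sign from camera's direction.

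The scripts were tested on simulated data for the comparison of 2 knockdown with 2 control libraries, with reads drawn for 58072 peaks. At simulated changes of 1.25-fold, 1.5-fold, 2-fold and 3-fold they recovered 44%, 78%, 100% and 98% of 50 changed peaks each, with 12 false calls among 172. The changed peaks all had a mean of at least 5 CPM, so these rates do not cover lower peaks. In the data 34426 tested peaks had a mean below 2 on the log2 scale. No difference in background between libraries was simulated. For the gene lists, simulated over 14630 genes, a list raised 1.2-fold was called at the preset correlation and not with an estimated one, and 0 of 26 unchanged lists were called. The genes were drawn independently, so this does not show how often the preset correlation gives false list calls where genes vary together. In the data the estimated correlation of the called lists ranged from -0.02 (calcium handling) to 0.19 (G1/S). The work used R 4.3.3, limma 3.58.1, edgeR 4.0.16 and DESeq2 1.42.0.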

Results

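Chromatin carrying methylated lysine 4 of histone H3 (H3K4) was profiled by CUT&RUN, in which a nuclease tethered to an antibody cuts and releases the DNA around the bound mark. The cells were cardiomyocytes isolated from the hearts of newborn mice (postnatal day 1) and treated for 72 h with a control reagent or with a short hairpin RNA against Kdm5b, which encodes an H3K4 demethylase. The title of the series names the question, whether Kdm5b controls the cell-cycle genes of cardiomyocytes. The methylation state that the antibody recognised and the antibody used for the negative control were not given in the sources used here. The cell type label also carries a postnatal number (P1 to P5) that differs between the 5 samples, whereas the isolation protocol gives postnatal day 1 for all of them. Day 1 is taken from the protocol. If the label were the age, age would differ between the libraries of every comparison below and could not be told apart from the knockdown.

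The table held 85275 peaks assigned to 25017 gene symbols, with a median width of 370 bp and a range from 198 to 40924 bp. It covered 2 control libraries, 2 knockdown libraries and 1 negative control library from control-treated cells. The libraries of a group are called 3 and 4 after their columns. The sample titles number them otherwise, so a column stands for its group and not for a particular titled sample. Reads in peaks came to 18710132 and 19001373 in control libraries 3 and 4, to 21285387 and 31068085 in knockdown libraries 3 and 4, and to 3784381 in the negative control. At this depth 1 read was worth 0.0534, 0.0526, 0.0470, 0.0322 and 0.264 CPM in the same order. Across peaks, Pearson's r of the log2 values was 0.985 between the control libraries, 0.988 between the knockdown libraries and 0.983 to 0.988 between a control and a knockdown library, so the groups do not separate by r, and peaks are not independent replicates. The libraries of each pair differed by more than sampling noise, with a chi-square of 2.84 per peak between the controls and 4.75 between the knockdown libraries, against 3.86 to 8.48 between groups. Nothing in the labels says that the libraries of a group came from separate cultures or animals, so limma's p-values below measure only the spread between these libraries, which may be technical. Camera at the preset correlation compares the genes of a list with other genes. Its p-values rest on the spread between genes and are not evidence from replicate libraries. Values are given as mean ± SD with n = 2 per group, and the negative control is a single library without a spread.

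The H3K4 libraries were first set against the negative control, which gives the background measured the same way. Each library is scaled to its own reads in peaks, so equal CPM does not mean equal background. Peaks under 500 bp took 21.9% of the negative control's reads and 6.23% of those in the control libraries. All ratios to the negative control given below carry this limit. Gata4, which encodes a cardiac transcription factor, had a peak on chromosome 14 from 63465788 to 63491472 (GRCm39) with 576 ± 9.71 CPM in the control libraries, 588 ± 12.1 CPM in the knockdown libraries and 278 CPM in the negative control. Ccnd2, the cyclin D2 gene, had 267 ± 1.19 CPM in the control libraries against 122 CPM in the negative control. Other genes stood near or below the negative control. Myh6, the gene of the alpha myosin heavy chain, had 231 ± 4.30 CPM against 229 CPM, and Nppa, which encodes atrial natriuretic peptide, had 26.7 ± 0.608 CPM against 36.7 CPM.

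Of 58072 peaks tested, 3220 (5.54%) stood at least 2-fold above the negative control in the control libraries and 3949 (6.80%) in the knockdown libraries, and 3132 peaks were shared. Among all peaks, tested or not, most that passed this level over the 4 H3K4 libraries were at least 2 kb wide. They were 2552 of the 9750 peaks from 2 kb to under 5 kb (26.2%) and 894 of the 2065 peaks of at least 5 kb (43.3%). Of the 52643 peaks under 500 bp 3 passed (0.0057%). In the control libraries 35522 tested peaks (61.2%) lay at least 2-fold below the negative control. By gene list, the ribosomal protein genes had a median log2 ratio of H3K4 to negative control of 1.13, and random lists of the same peak height ranged from 0.75 to 1.11. The median was 0.08 for the sarcomere genes, where random lists ranged from 0.78 to 1.15. For the epicardial markers it was -1.13 (random lists -0.19 to 0.81), and for developmental regulators of other lineages it was -1.73 (random lists -0.92 to -0.01). With 1 negative control library there is no test of these ratios, and 3 reads, the floor of that library, correspond to 0.793 CPM. Such floors, and the binomial interval given further on, cover counting error only.

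Kdm5b itself was examined first in the comparison of knockdown with control. Its peak, on chromosome 1 from 134483258 to 134485368, held 46.3 and 43.6 CPM in the control libraries, 40.7 and 46.2 CPM in the knockdown libraries and 21.9 CPM in the negative control. The log2 fold change was -0.05 (SE 0.08, limma adjusted p = 0.794). H3K4 signal at the gene does not measure the mRNA that a hairpin RNA targets, so this value does not check the knockdown. Kdm5c, the gene of a related demethylase, had 92.9 ± 0.110 CPM in the control and 96.5 ± 1.47 CPM in the knockdown libraries (adjusted p = 0.675), and Kdm5a was not analysed here.

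Krt7, a keratin gene, had one of the largest rises. It rose from 16.01 ± 0.725 to 27.1 ± 2.20 CPM at its peak on chromosome 15 from 101308903 to 101311905, a log2 fold change of 0.72 (SE 0.10, limma adjusted p = 1.7e-08). Upk3b and Upk1b, which encode uroplakins, rose 1.63-fold (12.9 ± 1.30 to 21.5 ± 0.0673 CPM, chromosome 5 from 136067166 to 136069529) and 1.56-fold (15.5 ± 1.26 to 24.7 ± 0.747 CPM, chromosome 16 from 38617984 to 38620684). Muc16, a mucin gene, rose 1.76-fold on chromosome 9 from 18583411 to 18585079, from 3.58 ± 0.602 to 7.03 ± 0.751 CPM. The interferon-inducible gene Ifi27l2a showed a 1.84-fold rise on chromosome 12 from 103407909 to 103410166, from 9.61 ± 1.45 to 18.5 ± 2.46 CPM. Cyp4f39, Cmklr1, Crb2 and Slc39a10 were also among the largest, with rises between 1.61-fold and 1.65-fold. In the control libraries each of these peaks lay below the negative control, at 0.150 (Cyp4f39) to 0.366 (Upk3b) of its CPM.

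Leaving aside Gm numbers, among which the peak at Gm24105 fell further (log2 fold change -1.98), the largest falls were at Ncoa1, which encodes a nuclear receptor coactivator, and Malt1, which encodes a paracaspase. At Ncoa1 (chromosome 12, 4467733 to 4468032) the signal fell from 15.3 ± 0.0918 to 3.71 ± 0.0070 CPM, a log2 fold change of -1.79 (SE 0.15, limma adjusted p = 1.4e-26). At Malt1 (chromosome 18, 65560550 to 65560982) it fell from 12.8 ± 2.15 to 3.27 ± 0.622 CPM, a log2 fold change of -1.69 (SE 0.16). Both peaks were under 500 bp wide and held 73.5 and 63.7 CPM in the negative control. The homeobox genes Hmx2 (9.02 ± 0.699 to 4.77 ± 1.17 CPM) and Six3 (8.46 ± 0.655 to 4.48 ± 0.0305 CPM) and the fatty acid transporter gene Slc27a1 (14.1 ± 0.679 to 7.77 ± 0.568 CPM) were also among the 10. The others were Cdsn, Grik3, Rasl10b, Sptbn1 and Celf5, with log2 fold changes from -0.96 to -0.80. All 10 lay below the negative control too, with 39.9 CPM at Hmx2 and 30.9 CPM at Slc27a1 in that library.

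In all, limma called 773 peaks higher and 947 lower in the knockdown libraries among the 58072 tested, at 768 and 823 genes. The changes were small: the median log2 fold change was 0.24 among the higher and -0.51 among the lower peaks, and 21 rises and 350 falls exceeded 1.5-fold. Of the higher peaks 315 stood at least 2-fold above the negative control, and of the lower peaks 11 did. The median over all tested peaks was -0.14, and it followed peak height, from -0.24 at the weakest class of peaks (below 2 on the log2 scale) to 0.06 at the strongest (7 and above). Peaks under 500 bp that lay below the negative control took 6.22% ± 0.610 of the reads in the control libraries and 4.63% ± 1.41 in the knockdown libraries, a difference with an exact permutation p = 0.333, the smallest that 2 against 2 libraries allow. By library this share was 6.65% and 5.79% in control libraries 3 and 4, and 5.63% and 3.64% in knockdown libraries 3 and 4. Knockdown library 3 thus lay close to control library 4. The share was 21.9% in the negative control (exact 95% binomial interval 21.86% to 21.95%). CPM fixes each library's total, so a gain or loss of the mark over the whole genome cannot be read from these values. Without control library 3 or 4 the calls numbered 401 and 801, and without knockdown library 3 or 4 they numbered 783 and 349. Among the 3587 peaks at least 2-fold above the negative control, tested alone, 478 were higher and 13 lower. With quantile normalization 602 were higher and 797 lower, of which 893 were among the 1720, and with cyclic loess 526 and 856, of which 854 were. The calls fell to 55 higher and 34 lower with TMM scaling, to 28 and 3 with median centring and to 35 and 3 with DESeq2, and 0 peaks passed with limma without a trend (8226 at an unadjusted p of 0.05) or with scaling on narrow background peaks (1770).

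**Figure D1:**
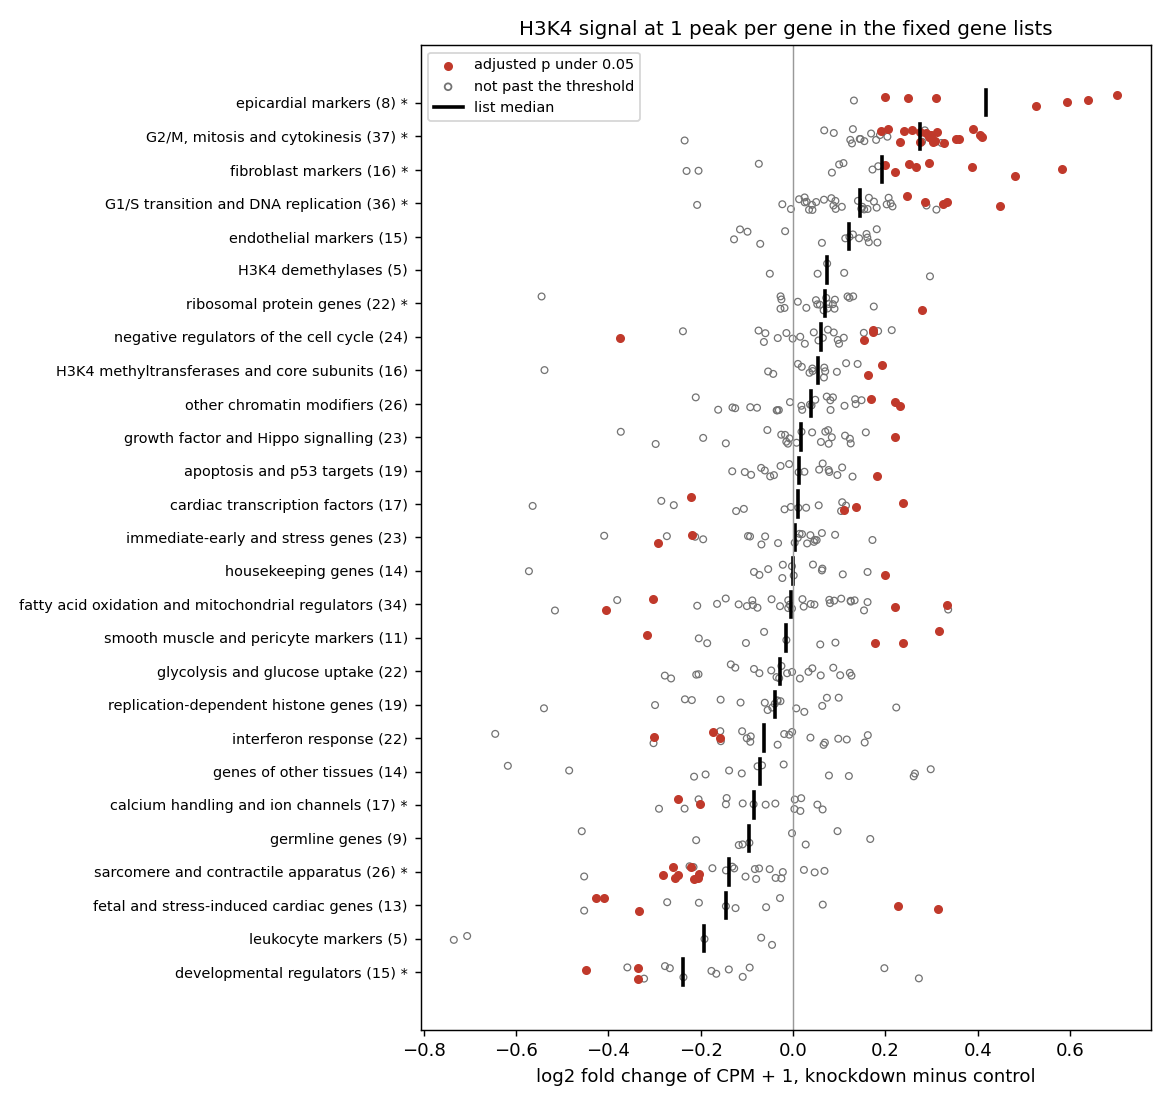
Log2 fold change (horizontal axis, knockdown minus control on the log2(CPM + 1) scale) of each measured member of 27 gene lists, 1 peak per gene, with filled points past limma's adjusted p of 0.05, vertical bars at list medians and stars on lists called by camera. The medians run from 0.42 for the epicardial markers to -0.24 for the developmental regulators. The median of the latter is -0.16 with quantile normalization and -0.15 with cyclic loess, but 0.0018 with median centring and 0.21 with scaling on narrow background peaks.

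Genes of the later cell cycle were mostly higher in the knockdown libraries. Of the 37 measured genes of G2/M, mitosis and cytokinesis, 21 rose and 0 fell (26 and 0 adjusted over the list alone), 36 had a positive fold change and the list median was 0.28, or 1.21-fold. Top2a, the gene of the mitotic topoisomerase, rose from 40.9 ± 0.597 to 54.5 ± 0.401 CPM (chromosome 11, 98912851 to 98916095, log2 fold change 0.40, SE 0.08, limma adjusted p = 5.9e-05). Ccna2, which encodes cyclin A2, rose from 39.5 ± 0.957 to 52.8 ± 2.34 CPM on chromosome 3 from 36623060 to 36627036. The kinase genes Plk1 (85.8 ± 0.413 to 106 ± 3.11 CPM) and Aurkb (47.8 ± 1.24 to 61.6 ± 0.899 CPM) rose as well, as did the proliferation marker gene Mki67 (63.1 ± 0.914 to 78.6 ± 4.46 CPM) and Cdk1 (74.0 ± 3.25 to 85.5 ± 1.02 CPM). Camera gave the G2/M list an adjusted p = 7.2e-22, and adjusted p = 0.189 with an estimated correlation. Its median was 0.23 with quantile normalization and with cyclic loess. These genes had little signal over the negative control, with a median log2 ratio of 0.39, near the lower end of random lists of the same height (0.37 to 0.76). At Ccna2 the control libraries lay below the negative control (43.6 CPM), and at Cdk1, Mki67 and Aurkb they held 1.23, 1.24 and 1.49 times its CPM.

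Of the 36 genes of the G1/S transition and DNA replication, 5 rose and 0 fell (10 and 0 adjusted over the list alone), with a median of 0.14 (camera adjusted p = 2.0e-07, adjusted p = 0.497 with an estimated correlation). The 5 were Mcm3 (16.5 ± 0.494 to 23.0 ± 0.230 CPM) and Mcm2 of the replicative helicase, the origin recognition gene Orc1 (68.6 ± 0.0745 to 86.7 ± 0.855 CPM), Rrm1 and Rfc4. Among peaks at least 2-fold above the negative control only 9 members were left, their median was 0.05 and the list stood below other genes (camera adjusted p = 0.620). The G1 cyclin genes did not pass: Ccnd1 had a log2 fold change of 0.03 (SE 0.05), Ccnd2 0.01 (SE 0.04) and Ccne1 0.03 (SE 0.09). Ccnb1 (0.09, SE 0.07), Cdk4 (0.11, SE 0.06) and E2f1 (0.09, SE 0.07) did not pass either. Among 24 negative regulators of the cell cycle, 3 rose (Meis2, Trp53 and Cdkn2c) and Cdkn1c fell, from 34.9 ± 0.631 to 26.7 ± 1.504 CPM (6 and 2 adjusted over the list alone, camera adjusted p = 0.056, called higher in 3 of 20 other settings, lowest adjusted p = 0.021). Cdkn1a (-0.06, SE 0.05), Cdkn1b (0.05, SE 0.08) and Meis1 (-0.24, SE 0.08, limma adjusted p = 0.061) did not pass. Of 19 replication-dependent histone genes, whose near-identical copies can share reads, 0 changed (0 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.265, called lower in 2 of 19 other settings, lowest adjusted p = 0.0074). In the same libraries the medians of the epicardial and fibroblast markers were 0.42 and 0.19, and that of the sarcomere genes was -0.14.

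**Figure D2:**
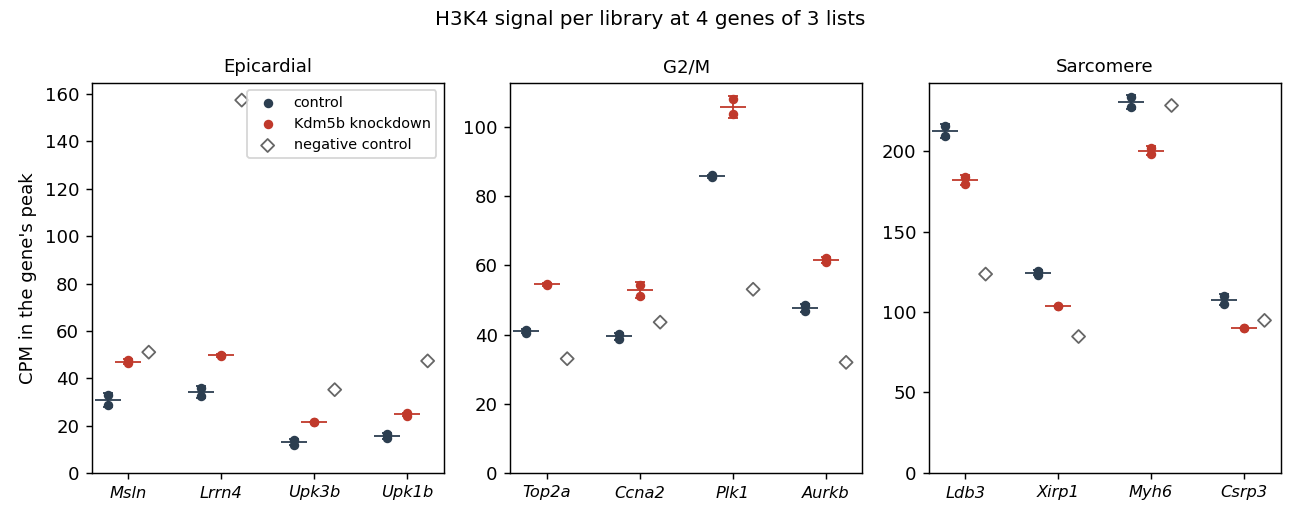
CPM (vertical axis, from 0) in the peak of the 4 genes with the smallest p in the epicardial, G2/M and sarcomere lists, with points for libraries, bars for mean ± SD (n = 2) and diamonds for the negative control. At Top2a the control libraries average 40.9 CPM and the knockdown libraries 54.5 CPM, whereas at Myh6 they average 231 and 200 CPM. The log2 fold change of Myh6 is -0.25 with quantile normalization and -0.32 with cyclic loess, but 0.04 with median centring and 0.25 with scaling on narrow background peaks.

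Genes of the contractile apparatus moved the other way. Of 26 sarcomere genes 0 rose and 8 fell (0 and 13 adjusted over the list alone), and 23 had a negative fold change, with a median of -0.14, or 0.909-fold (camera adjusted p = 3.6e-09, adjusted p = 0.189 with an estimated correlation). Ldb3, a Z-disc gene, fell from 213 ± 4.20 to 182 ± 3.08 CPM (chromosome 14, 34302241 to 34312858, limma adjusted p = 0.00032), and Myh6 fell from 231 ± 4.30 to 200 ± 2.82 CPM (chromosome 14, 55197771 to 55209412, adjusted p = 0.00081). Xirp1 (124 ± 1.68 to 104 ± 0.0731 CPM) and Csrp3 (108 ± 3.43 to 90.0 ± 0.109 CPM) fell as well. Tnnt2, the cardiac troponin T gene, had 186 ± 3.39 and 169 ± 4.23 CPM and did not pass (limma adjusted p = 0.058). Of 17 genes of calcium handling and ion channels 0 rose and 2 fell, the potassium channel gene Kcnh2 (96.8 ± 1.21 to 81.4 ± 2.57 CPM) and the ryanodine receptor gene Ryr2 (156 ± 0.661 to 135 ± 1.75 CPM). Adjusted over the list alone 4 fell, and the median was -0.09, at the lower edge of random lists matched on height and on signal over the negative control (-0.09 to 0.08, camera adjusted p = 0.0052, adjusted p = 0.403 with an estimated correlation). The sign of these falls and the list calls depend on the scaling. With quantile normalization and cyclic loess the sarcomere median was -0.19 and -0.21, and the calcium handling median was -0.14 with both. The lists were called lower in 14 and 12 of 19 other settings, respectively. The sarcomere median was -0.03 with TMM, 0.10 with median centring and 0.31 with scaling on narrow background peaks, and the call was lost in each (camera adjusted p = 0.066, 0.257 and 0.894). The calcium handling median was 0.02, 0.15 and 0.36 with the same scalings (adjusted p = 0.513, 0.769 and 0.926), and that call was also lost without a trend (0.072) and with all peaks of a gene averaged (0.061). On narrow background peaks the fold change was positive at every list member named as falling except Foxa1, and 0 peaks passed. Under each of these the median of all peaks was also higher than -0.14, by 0.07 with TMM, 0.24 with median centring and 0.31 on narrow background peaks (0.14 with quantile normalization and 0.15 with cyclic loess). The median of the strong peaks, to which most of these genes belong, rose from 0.06 to 0.17, 0.30 and 0.51 with those 3 scalings, so the change of sign is a shift shared with other strong peaks.

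Fetal and stress-induced cardiac genes were mixed. Of 13 measured, 3 fell (Nppa from 26.7 ± 0.608 to 19.9 ± 0.451 CPM, Cacna1h and Tnni1) and 2 rose (Acta2, the smooth muscle actin gene, from 88.3 ± 3.89 to 110 ± 2.27 CPM, and Dab2). Adjusted over the list alone 2 rose and 5 fell, and the list was not called (median -0.15, camera adjusted p = 0.052), but it was called lower in 5 of 19 other settings (lowest adjusted p = 0.00034). Among 17 cardiac transcription factors Mef2c (144 ± 6.67 to 170 ± 0.652 CPM), Gata6 and Hand2 rose and Irx4 fell (4 and 2 adjusted over the list alone, camera adjusted p = 0.265). The list was called higher among peaks 2-fold above the negative control (adjusted p = 0.0045) and lower with cyclic loess (adjusted p = 0.00017). Gata6 and Hand2 did not keep that direction under cyclic loess scaling, with -0.01 and -0.05. Gata4 had a log2 fold change of 0.03 (SE 0.03) and did not pass, but under cyclic loess scaling it was -0.12 with an adjusted p = 0.00028, where adjusted p over all alternatives ranged from 0.00028 to 0.973. Of 34 genes of fatty acid oxidation and mitochondrial regulation Nrf1 and Ucp2 rose and Esrrb and Cpt1b fell (6 and 5 adjusted over the list alone, camera adjusted p = 0.730). Of 22 glycolysis genes 0 passed, also adjusted over the list alone (camera adjusted p = 0.564), but the list was called lower with quantile normalization (adjusted p = 0.00066) and cyclic loess (adjusted p = 3.4e-05). Gapdh had 173 ± 4.62 and 164 ± 9.42 CPM, a log2 fold change of -0.07 that was -0.13 with quantile normalization and -0.17 with cyclic loess, but 0.04 with TMM, 0.17 with median centring and 0.38 on narrow background peaks. It was called lower in 2 of 19 other settings (lowest adjusted p = 0.0031). Beside these lists, 7 of 8 epicardial and 8 of 16 fibroblast markers were called higher in the same libraries, and both list calls were lost with an estimated correlation (adjusted p = 0.189).

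Markers of other heart cell types were examined for the same reason, since such cells can be present in cardiomyocyte preparations. Epicardial markers rose: 7 of 8 passed, also adjusted over the list alone, with a median of 0.42, or 1.34-fold (camera adjusted p = 1.3e-15, adjusted p = 0.189 with an estimated correlation). They included the mesothelin gene Msln (30.9 ± 2.96 to 47.0 ± 1.08 CPM, chromosome 17, 25970182 to 25973889, limma adjusted p = 3.4e-09), Lrrn4 (34.2 ± 2.55 to 49.6 ± 0.501 CPM, adjusted p = 1.8e-07) and the transcription factor gene Wt1 (94.3 ± 3.43 to 112 ± 2.67 CPM). Of 16 fibroblast markers 8 rose and 0 fell (10 and 0 adjusted over the list alone), with a median of 0.19 (camera adjusted p = 6.1e-10, adjusted p = 0.189 with an estimated correlation). Thy1 rose from 21.5 ± 0.890 to 32.8 ± 3.41 CPM, the collagen gene Col3a1 from 34.3 ± 0.750 to 48.3 ± 4.15 CPM and the decorin gene Dcn from 54.8 ± 4.80 to 71.9 ± 2.25 CPM. Col1a1 had 73.5 ± 0.653 and 83.7 ± 3.92 CPM and did not pass (limma adjusted p = 0.081). With quantile normalization and cyclic loess the epicardial median was 0.37 and 0.40 and the fibroblast median 0.17 and 0.15.

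Of 15 endothelial markers 0 passed, also adjusted over the list alone (median 0.12, camera adjusted p = 0.064, called higher in 4 of 19 other settings, lowest adjusted p = 0.012), and Pecam1 had 24.96 ± 1.21 and 28.1 ± 0.0978 CPM. Among 11 smooth muscle and pericyte markers Tagln (87.9 ± 4.45 to 110 ± 1.22 CPM), Pdgfrb and Smtn rose and Abcc9 fell (3 and 1 adjusted over the list alone, camera adjusted p = 0.406). Of 5 measured leukocyte markers 0 passed (0 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.155, called lower with scaling on narrow background peaks, adjusted p = 0.039), and the erythroid list, with 3 measured members, was too short to test.

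Genes of chromatin and housekeeping functions moved little. Of 5 H3K4 demethylase genes 0 passed, also adjusted over the list alone (camera adjusted p = 0.265), and of 16 genes of H3K4 methyltransferase complexes Kdm6a and Men1 rose (2 and 0 adjusted over the list alone, camera adjusted p = 0.072, called higher in 3 of 20 other settings, lowest adjusted p = 0.010). Of 26 other chromatin modifier genes Ehmt1, Ehmt2 and Tet2 rose and 0 fell (4 and 2 adjusted over the list alone, camera adjusted p = 0.234). Ehmt2, which encodes an H3K9 methyltransferase, went from 130 ± 2.44 to 152 ± 7.18 CPM. The ribosomal protein list was called higher with a median of 0.07 (camera adjusted p = 0.026, adjusted p = 0.550 with an estimated correlation), although Rpl4 alone rose of its 22 members (2 and 0 adjusted over the list alone). Its median was within that of random lists of the same height (0.0098 to 0.11), so these genes were no higher than other peaks of their height. The call was kept in 9 of 20 other settings. It was lost without control library 3 (camera adjusted p = 0.162) or knockdown library 4 (0.083), with quantile normalization (0.746), cyclic loess (0.893), median centring (0.133) and scaling on narrow background peaks (0.396), with a filter of 5 CPM (0.102), among peaks 2-fold above the negative control (0.620) and without a trend (0.063). Of 14 housekeeping genes Tubb5 rose and 0 fell (2 and 0 adjusted over the list alone, camera adjusted p = 0.495), and Actb had 156 ± 0.0169 and 161 ± 2.05 CPM, with a log2 fold change of 0.04 that was 0.15 with TMM, 0.28 with median centring and 0.50 on narrow background peaks, but -0.0099 with quantile normalization and -0.05 with cyclic loess.

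Of 15 measured developmental regulators of other lineages 0 rose and 3 fell (1 and 6 adjusted over the list alone), with a median of -0.24 (camera adjusted p = 0.00062, adjusted p = 0.497 with an estimated correlation). Random lists matched on height and on signal over the negative control had medians from -0.25 to -0.02, so the list does not stand out from them. The 3 were Eomes (43.2 ± 1.40 to 34.0 ± 1.70 CPM), Foxa1 (21.0 ± 0.483 to 15.1 ± 0.976 CPM) and Neurog2 (37.9 ± 0.564 to 29.9 ± 3.38 CPM), which stood at 120, 51.8 and 88.5 CPM in the negative control. The list was called lower in 13 of 19 other settings, and its median was -0.13 with TMM, -0.16 with quantile normalization and -0.15 with cyclic loess. The list's median was 0.0018 with median centring and 0.21 with scaling on narrow background peaks, with the call lost in both (camera adjusted p = 0.133 and 0.675). The call was also lost without knockdown library 3 and with all peaks of a gene averaged (0.074).

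The remaining lists were not called with the deposited CPM. Of 22 interferon response genes Rsad2, Ifit1 and Mx2 fell and 0 rose (2 higher and 5 lower adjusted over the list alone, camera adjusted p = 0.143), with Rsad2 at 76.3 ± 8.37 and 61.7 ± 6.11 CPM, but Ifit1 and Mx2 were at 0.07 and 0.08 with median centring, and Rsad2, Ifit1 and Mx2 at 0.15, 0.28 and 0.30 on narrow background peaks. The list was called lower with quantile normalization (adjusted p = 0.00027), with cyclic loess (0.00011), without control library 4 (0.016) and among peaks 2-fold above the negative control (0.00023). Of 23 stress and immediate-early genes Trib3 and Hmox1 fell (1 higher and 5 lower adjusted over the list alone, camera adjusted p = 0.205, called lower in 2 of 20 other settings, lowest adjusted p = 2.3e-06). Among 23 growth factor and Hippo signalling genes Nrg1, the neuregulin gene, rose from 92.4 ± 3.82 to 108 ± 4.92 CPM (2 and 1 adjusted over the list alone, camera adjusted p = 0.324, called lower with cyclic loess, adjusted p = 0.015). Among 19 apoptosis and p53 genes Ccng1 rose from 104 ± 4.03 to 118 ± 0.837 CPM (1 and 0 adjusted over the list alone, camera adjusted p = 0.455, called lower with cyclic loess, adjusted p = 0.019). None of the 9 germline genes passed, also adjusted over the list alone (camera adjusted p = 0.700), and 0 of 14 genes of other tissues did (0 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.659). Median, mean and test differed in sign for the cardiac transcription factors (0.01, -0.04, higher), the fatty acid oxidation genes (-0.0047, -0.02, higher), the smooth muscle markers (-0.01, -0.00025, higher), the stress genes (0.0037, -0.06, lower) and the housekeeping genes (-0.00037, -0.01, higher).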

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

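The count of changed peaks, 1720 (773 higher and 947 lower), depended on the scaling, the variance model and single libraries. It was 491 (478 and 13 of 3587) among peaks at least 2-fold above the negative control, 89 (55 and 34) with TMM scaling, 31 (28 and 3) with median centring, 0 with limma without a trend and 3853 (1578 and 2275) with the number in the column names as a block, a pairing whose check value was a correlation of 0.118. With 1 library left out it ranged from 349 to 801. At an adjusted p of 0.10 it was 2732, and at an unadjusted p of 0.05 it was 9653. The added settings, edgeR, DESeq2, cyclic loess and narrow-peak scaling, were chosen after seeing the data. The count was 89 (51 and 38) with edgeR and TMM, 38 (35 and 3) with DESeq2 and 0 with scaling on narrow background peaks. The residual SD at strong peaks was 0.0671 with the deposited CPM, 0.112 with TMM, 0.171 with median centring and 0.360 on narrow background peaks, and the cause of the lost calls was not tested.

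The median log2 fold change of all tested peaks, -0.14, was 0.0043 with a filter of 5 CPM, 0.081 among peaks 2-fold above the negative control, 0.0027 with quantile normalization, 0.10 with median centring, 0.0088 with cyclic loess, 0.013 with DESeq2 and 0.17 with scaling on narrow background peaks. With 1 library left out it ranged from -0.25 to -0.059. The number of called lists, 8, was 13 with quantile normalization (7 shared), 4 with median centring (4 shared), 16 with cyclic loess (7 shared), 5 with scaling on narrow background peaks (4 shared), and 0 with an estimated correlation or with fry. Among peaks 2-fold above the negative control it was 2 of 12 lists with enough members, the cardiac transcription factors (adjusted p = 0.0045) and the interferon response genes (adjusted p = 0.00023), and 0 of the 8 were called. Of those 8, only the G1/S and ribosomal protein lists could be tested there, each with an adjusted p = 0.620. The share of peaks 2-fold above the negative control, 5.54%, was 0.0034% at 4-fold, 4.35% with a pseudocount of 5, 3.78% without a filter, and 6.39% and 7.24% with knockdown library 3 or 4 alone. The cause of these differences was not tested.

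Several values changed sign. Median centring adds 0.24 to every peak, so its changes of sign restate that shared shift. With it the log2 fold changes were 0.036 for Myh6, 0.037 for Ryr2, 0.017 for Irx4, 0.067 for Ifit1, 0.082 for Mx2, 0.017 for Ldb3 and 0.021 for Hmox1. With DESeq2 they were 0.012 for Myh6, 0.013 for Ryr2, 0.045 for Ifit1, 0.062 for Mx2 and 0.0031 for Hmox1. With cyclic loess they were -0.12 for Gata4, -0.011 for Gata6 and -0.047 for Hand2, and the list medians were -0.085 for cardiac transcription factors, -0.058 for growth and Hippo signalling and -0.060 for apoptosis and p53 genes. Among peaks 2-fold above the negative control the G1/S median was 0.050, with the list below other genes.

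Scaling on narrow background peaks likewise raised the median of strong peaks, from 0.06 to 0.51. With it the log2 fold changes were 0.25 for Myh6, 0.028 for Nppa, 0.20 for Kcnh2, 0.25 for Ryr2, 0.23 for Irx4, 0.067 for Cdkn1c, 0.11 for Eomes, 0.11 for Neurog2, 0.032 for Esrrb, 0.14 for Cpt1b, 0.021 for Cacna1h, 0.11 for Tnni1, 0.15 for Rsad2, 0.28 for Ifit1, 0.30 for Mx2, 0.13 for Abcc9, 0.23 for Ldb3, 0.19 for Xirp1, 0.19 for Csrp3, 0.16 for Trib3 and 0.23 for Hmox1. The calcium handling median was 0.36.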

Other observations

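Of the 10 explanations tested here, those for the G2/M list, for the 3 narrow peaks and for the share of cardiomyocytes were chosen only after the result was seen, while the flank test and the background test of the sarcomere list were written before.

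Peaks under 500 bp beside strong peaks did not gain signal over isolated ones. With cyclic loess, 744 flanking and 22559 isolated narrow peaks differed by a mean of 0.015 over the 4 pairs of a control with a knockdown library, from -0.02 to 0.04, and the control libraries differed from each other by 0.05. Spreading of the mark into the flanks is not seen in these separately called peaks. Of all 52643 peaks under 500 bp, 41 lay above the negative control. Spreading that widened a strong peak itself would not be counted here, so the test cannot exclude it.

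The rise of the G2/M list was weighed against background and cell composition. With cyclic loess the G2/M median was still 0.23 (camera adjusted p = 6.6e-23), so a background difference that follows peak height does not explain it. Random lists matched on height and on signal over the negative control had medians from -0.01 to 0.09, below the list's 0.28. Other kinds of background difference were not tested. The 4 marker lists of other cell types did not rise alike (permutation p = 0.00042, shuffling marker genes and not libraries). The lists also differ in signal over the negative control, with a median log2 ratio of -1.13 for epicardial and -0.23 for fibroblast markers. Unequal rises therefore do not decide whether these cell types increased together. More epicardial and fibroblast cells in the knockdown cultures could raise cell-cycle genes too: the G2/M median exceeded that of their markers by 0.040. The 95% bootstrap interval of this difference over list genes, from -0.09 to 0.11, carries no spread between libraries. A rise within cardiomyocytes is also possible. The G2/M median of 0.28 lies above the 0.091 that bounds random lists matched on height, but this restates the rise and does not say which cells carry it. An increase of epicardial and fibroblast cells and a rise within cardiomyocytes cannot be told apart here.

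The fall of the sarcomere list was weighed against background and a lower share of cardiomyocytes. Random lists matched on height and on signal over the negative control had medians down to -0.062, and the list's -0.14 lies below them. A background difference shared by genes of that height and ratio is therefore not the whole cause. The fetal heart, glycolysis, interferon response and replication-dependent histone lists, which camera did not call, also lay below their random lists. Peak width was not matched, the draws carry no spread between libraries, and other kinds of background difference were not tested. The sarcomere and calcium handling medians differed by -0.053 (95% bootstrap interval over list genes -0.18 to 0.06, without the spread between libraries). The fall also depends on the scaling and the test. The sarcomere median was -0.03 with TMM, 0.10 with median centring and 0.31 on narrow background peaks, with the call lost in each. It was also lost with an estimated correlation in camera and with fry (adjusted p = 0.189 and 0.069). If the fall stands, it may mean fewer cardiomyocytes in the knockdown cultures or a change within them, and these cannot be told apart here.

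The falls at Ncoa1 and Malt1 go with that of another narrow peak, at Gm24105 on chromosome 5 from 149184748 to 149185119, which fell from 30.2 ± 0.217 to 6.94 ± 0.888 CPM and held 162 CPM in the negative control. With cyclic loess, which removes a trend shared by peaks of the same height, all 3 stayed past the threshold, with log2 fold changes of -1.52 or lower (largest adjusted p = 5.8e-19), so such a trend is not the whole cause, although with scaling on narrow background peaks, where 0 peaks passed, Ncoa1 was at -1.39 and Malt1 at -1.31 (adjusted p = 0.787 for both). The negative control exceeded the control libraries by at least 2.19 on the log2 scale at all 3. Over 25590 other tested peaks under 500 bp the median excess was 1.22. The 3 peaks thus showed no H3K4 signal above the negative control. Each library is scaled to its own total, so this ratio cannot exclude a loss of the mark. DNA of a single source in the control-treated cells could have aligned to all 3 places, but the chi-square test of equal proportions in the 3 libraries of those cells (p = 0.109) covers counting error only, so a shared source and separate ones cannot be told apart here. Knockdown libraries held 0.230, 0.243 and 0.256 of the control signal at Gm24105, Ncoa1 and Malt1.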
